A study of Mus musculus with 6 samples.

How the data were processed

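Per the labels, total RNA was extracted with Trizol from CAD cells in 2 groups of 3 biological replicates, transfected with a plasmid expressing miR-124a-2 or with the empty vector. Biotin-labelled cRNA was made from 6 ug of it by the standard Affymetrix procedure, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes, which give no version. The probe definition file and any filter are not stated. The 6 columns held 45101 probe sets and no missing value, and their sorted values differed by at most 0.19 at any rank, so no further normalization was applied for the reported values. Arrays give no read depth, and the number of arrays limits precision.

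Genes were named from the platform annotation of 2016. Of the probe sets, 34958 had 1 gene, 932 had several and 9211 were not listed. Of the 64 control probe sets, 51 were not listed and 13 had 1 gene and were kept; 1 gene was represented by a control probe set, and it did not pass. Probe sets without exactly 1 gene were not used for genes. Symbols were checked through the Entrez ID against a RefSeq gene table, which held 18033 of 18195 genes, and 0 symbols needed updating. Each gene was represented by its probe set with the highest mean over 6 arrays. For 9011 genes there was over 1 probe set, and those named by the rule below whose probe sets differed in sign are pointed out. No detection calls were used and dim genes were kept.

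Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values of single genes are from this fit, and errors of log2 fold changes are its standard errors. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 19 lists, and again with the correlation estimated from the data and with fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Members were also counted after adjustment over the list alone. Symbols of the lists were matched to current symbols or unique synonyms.

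The design, the lists, the rule for naming genes and the settings listed below were fixed before the data were examined. Named genes are Ptbp1, Ptbp2, Ctdsp1, Dlg4 and Rest. To these were added the 14 higher and 14 lower genes with the largest change among those that passed without overlap between groups, transcripts without a gene name passed over. From each list up to 4 members with the smallest adjusted p were taken, or, where none passed, up to 2 with the largest change, given as values. These settings were the replicate number as a block, leaving out each array, median centring, quantile normalization, cyclic loess, a filter on dim genes, an intensity trend with and without robust estimation, other rules for probe sets, all probe sets, and stricter thresholds. A test of miR-124 seed matches in 3′ untranslated regions was planned and not run, since 3′ untranslated regions were not analysed here.

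After the data were seen, further fits took as a block the array set (narrow or wide interquartile range, divided at the largest gap between arrays) or the batch by poly-A controls (divided likewise), or kept only replicates 2 and 3. The estimated correlation was also combined with either block. The model was tested on simulated data with the means and spreads of the 18195 genes and 200 changed genes in each of 20 draws. It found 25.7% of changes of 0.5 on the log2 scale, 79.1% of changes of 1, 93.8% of changes of 1.5 and 97.7% of changes of 2, and a mean of 4.35% of its calls fell on unchanged genes. A list shifted by -0.5 was called in 20 of 20 draws, and lists sharing no gene with it were called 0 times. These draws had independent genes and no array sets, and 9 other splits of the measured arrays called 2 to 9 lists.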

Results

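RNA was measured on 6 arrays from CAD cells, a mouse neuroblastoma line of catecholaminergic origin. The cells had received either a plasmid expressing miR-124a-2, a precursor of the brain-enriched microRNA miR-124, or the same kind of plasmid without it (empty vector). Each group had 3 biological replicates, and each array gave a log2 signal for 45101 probe sets. Signals ran from 2.59 to 14.39, the median per array lay between 4.72 and 4.83, and control probe sets for a bacterial transcript that is not added to the samples averaged 3.37 to 3.50. Correlations between arrays over 18195 genes were 0.989 to 0.998, and the number of arrays limits the precision of every value below.

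The arrays also differed in ways that followed the groups only in part or not at all. Empty vector replicate 1 and miR-124a-2 plasmid replicates 1 and 2 had interquartile ranges of 3.06 to 3.09 on the log2 scale (narrow arrays), against 3.26 to 3.34 in the other 3 (wide arrays). The 18S ribosomal RNA controls averaged 5.23 to 5.83 in the narrow arrays and 4.71 to 4.87 in the wide ones. Poly-A control transcripts, which are added to the RNA before labelling, averaged 5.93 and 5.88 in the replicate 1 arrays of both groups and 5.51 to 5.59 in the other 4. The log2 ratio of 3′ to 5′ signal of the transferrin receptor controls was 1.34 and 1.55 in the replicate 1 arrays and 0.95 to 1.09 in the others. More plasmid than empty vector arrays were narrow, so fold changes from fits without this block carry a part of the difference between the array sets. Values within the narrow and wide arrays are therefore given for Ptbp1, for some lists, and for named genes that passed and whose 2 values differed by over 1.5 times. The narrow values rest on a single empty vector array (replicate 1), and the wide values on a single plasmid array (replicate 3).

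The comparison of the groups asks which transcripts change when miR-124 is supplied to cells of neuronal lineage. Ptbp1, a splicing repressor of non-neuronal cells, fell from 12.02 ± 0.04 to 10.78 ± 0.22 (log2 signal, mean ± SD, n = 3 per group). Its log2 fold change was -1.24 ± 0.12 (SE, adjusted p = 0.00978), or 2.35-fold lower, with -1.31 within the narrow and -1.02 within the wide arrays. With the mean of its 3 probe sets, 1 of which was higher, Ptbp1 had -0.48 and did not pass (adjusted p = 0.0932, from 0.000912 to 0.193 over the alternatives). Ctdsp1, a phosphatase that works with the repressor REST, fell by 1.38 on the log2 scale (SE 0.19, adjusted p = 0.0177). Ptbp2, the neuronal counterpart of Ptbp1, had 8.57 ± 0.28 in the empty vector group and 9.58 ± 0.38 with miR-124a-2. That log2 fold change of 1.01 ± 0.20 did not pass (adjusted p = 0.0697). Ptbp2 passed in 7 of 18 alternatives, among them the replicate number, the poly-A batch or the array set as a block (adjusted p = 0.0107 with the last, from 0.0107 to 0.321 over the alternatives). Dlg4, which encodes the postsynaptic protein PSD-95, had a log2 fold change of 0.29 (adjusted p = 0.475), and Rest one of -0.15 (adjusted p = 0.801, 1 of 4 probe sets higher).

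Of 18195 genes, 165 changed at an adjusted p under 0.05, 38 higher and 127 lower with miR-124a-2. At least 2-fold changes were seen in 47 of them, 6 higher and 41 lower, and the median log2 fold change of all genes was 0.02. All 165 had values that did not overlap between groups, as did 2958 of the genes tested (16.3%, where chance gives 10%). With the array set as a block, 546 genes passed (259 higher, 287 lower), and these included all 165. The count depended on single arrays: it was 61 without empty vector replicate 1, and 0 without replicate 2 or replicate 3 of that group in limma (1285 and 1313 genes at an unadjusted p under 0.05). It was 13, 46 and 343 without miR-124a-2 plasmid replicates 1, 2 and 3, and 0 with the replicate 1 arrays of both groups left out (1825 at an unadjusted p under 0.05).

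**Figure D1:**
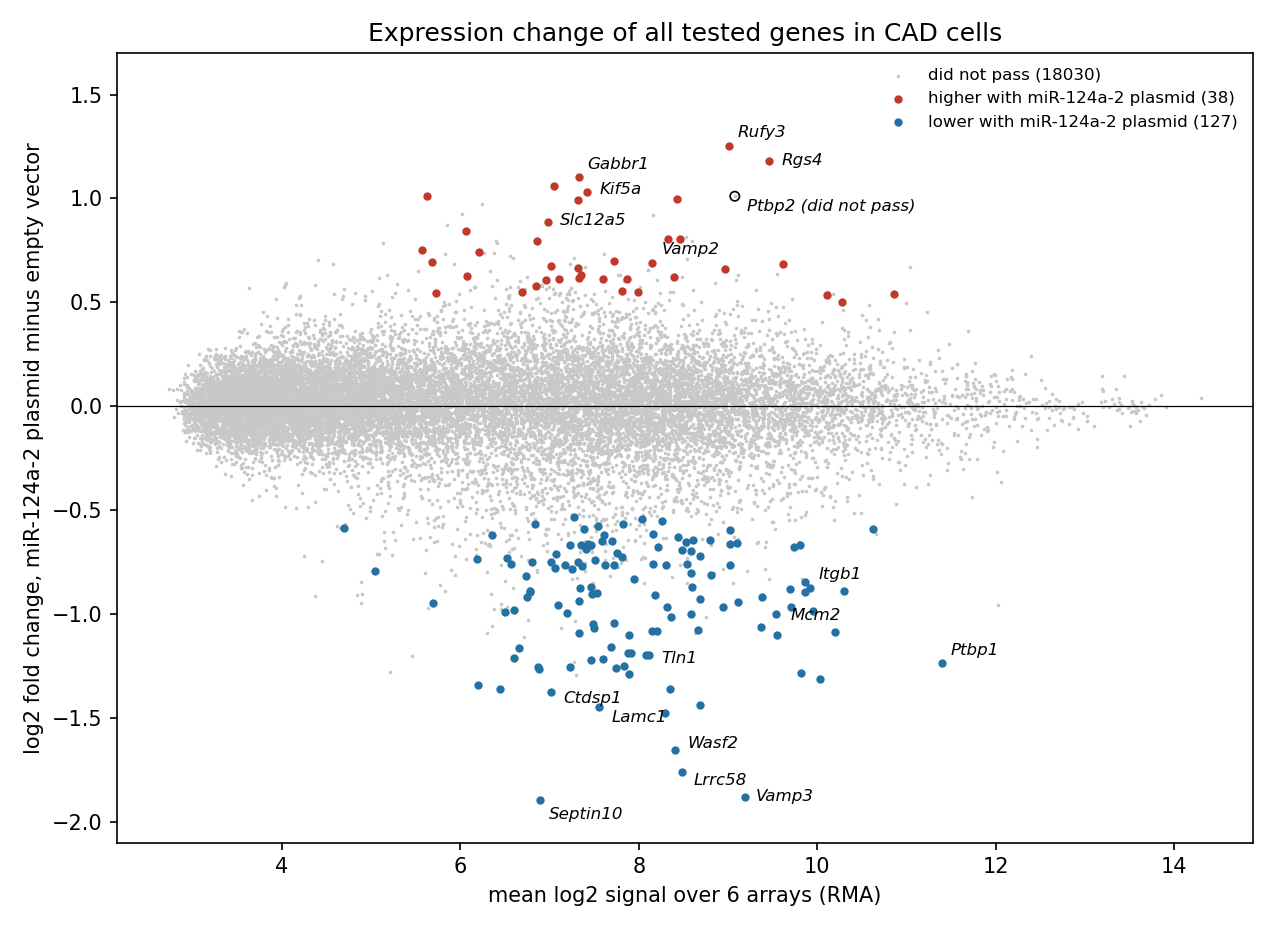
Log2 fold change (miR-124a-2 plasmid minus empty vector) of each of 18195 genes against its mean log2 signal over 6 arrays. Red points are the 38 genes that rose and blue points the 127 that fell, Ptbp1 being the brightest of those labelled, and the open circle is Ptbp2, which did not pass.

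The largest falls among named genes were in Septin10 and Vamp3. Septin10, a septin cytoskeletal protein, fell by 1.90 (SE 0.33, adjusted p = 0.0437), with -2.53 in the narrow and -1.02 in the wide arrays, and did not pass with the poly-A batch as a block (adjusted p = 0.0570, from 0.00409 to 0.344 over the alternatives). Vamp3, a SNARE protein of endosomal vesicles, fell by 1.88 (SE 0.15, adjusted p = 0.00978) in its brightest probe set, and all 5 of its probe sets were lower (-1.89 to -0.85). Lrrc58 fell by 1.76 (adjusted p = 0.0424), with -1.95 in the narrow and -1.06 in the wide arrays, and Wasf2, an activator of branched actin assembly, fell by 1.65 (adjusted p = 0.00978). Pttg1ip fell by 1.48, the laminin chain gene Lamc1 fell by 1.45 (-1.65 narrow, -0.95 wide), the mRNA decay factor gene Zfp36l2 fell by 1.44, and the NF-kappaB subunit gene Rela fell by 1.36. Gabpb2 decreased by 1.36 (-1.67 narrow, -0.87 wide), the metalloprotease gene Adam12 decreased by 1.34, Plp2 decreased by 1.31, and the succinyl-CoA ligase subunit gene Suclg2 decreased by 1.29. Iqgap1, a scaffold of the actin cortex, decreased by 1.29. The adjusted p of these last 9 genes lay between 0.00978 and 0.0308. Iqgap1 was represented by its brightest probe set, and 3 of its 7 probe sets had higher means with miR-124a-2, as did 1 of 3 for Zfp36l2. With the mean of probe sets, Lrrc58, Lamc1 and Zfp36l2 did not pass (-1.76, -0.88 and -0.64), and Pttg1ip, Gabpb2 and Iqgap1 passed with -0.92, -0.58 and -0.58. With the probe set of largest spread, Septin10, Lrrc58, Wasf2, Lamc1, Zfp36l2, Gabpb2 and Iqgap1 did not pass, nor did Septin10 and Lrrc58 with median centring. Under the rule of largest spread, all of these but Wasf2 (-1.66) kept the value of the main fit, so no change of probe set ended those calls. Lrrc58 has 1 probe set under any rule.

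The largest rise was in Rufy3, which encodes a protein of neuronal axons, at a log2 fold change of 1.25 (SE 0.15, adjusted p = 0.0121). Rgs4, a regulator of G-protein signalling, rose by 1.18 (adjusted p = 0.0107), and Gabbr1, a subunit of the GABA-B receptor, rose by 1.10 (adjusted p = 0.0121). The motor protein genes Kif5a and Klc1 rose by 1.03 and 1.00, and Dnm3, a dynamin enriched in brain, rose by 1.01. Sostdc1, a secreted inhibitor of BMP signalling, rose by 1.06, and Rec8, a cohesin subunit of meiosis, rose by 0.99. The neuronal chloride transporter gene Slc12a5 rose by 0.88 (0.57 narrow, 1.06 wide), Aldh1b1 by 0.84 (0.57 narrow, 0.99 wide), the G-protein subunit gene Gnao1 by 0.81, Nacad by 0.80, Tspan17 by 0.79 and the coronin gene Coro1a by 0.75. Adjusted p-values of these 14 genes lay between 0.00978 and 0.0481. Probe sets of the same gene differed in sign for Rufy3 (2 of 6 lower), Gabbr1 (1 of 4 lower), Klc1 (1 of 3 lower) and Gnao1 (2 of 3 lower). With the mean of probe sets, Gabbr1, Kif5a, Klc1, Dnm3, Gnao1 and Nacad did not pass (0.57, 0.53, 0.44, 0.48, 0.08 and 0.59), and Tspan17 passed with 0.52. With the probe set of largest spread, Gnao1 had -0.37, and Gnao1, Gabbr1, Dnm3, Sostdc1, Slc12a5, Aldh1b1, Tspan17 and Coro1a did not pass, nor did Gnao1 and Slc12a5 with median centring. Under the rule of largest spread, Gabbr1 and Sostdc1 had 1.16 and 1.01, and Dnm3, Slc12a5, Aldh1b1, Tspan17 and Coro1a kept the value of the main fit.

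**Figure D2:**
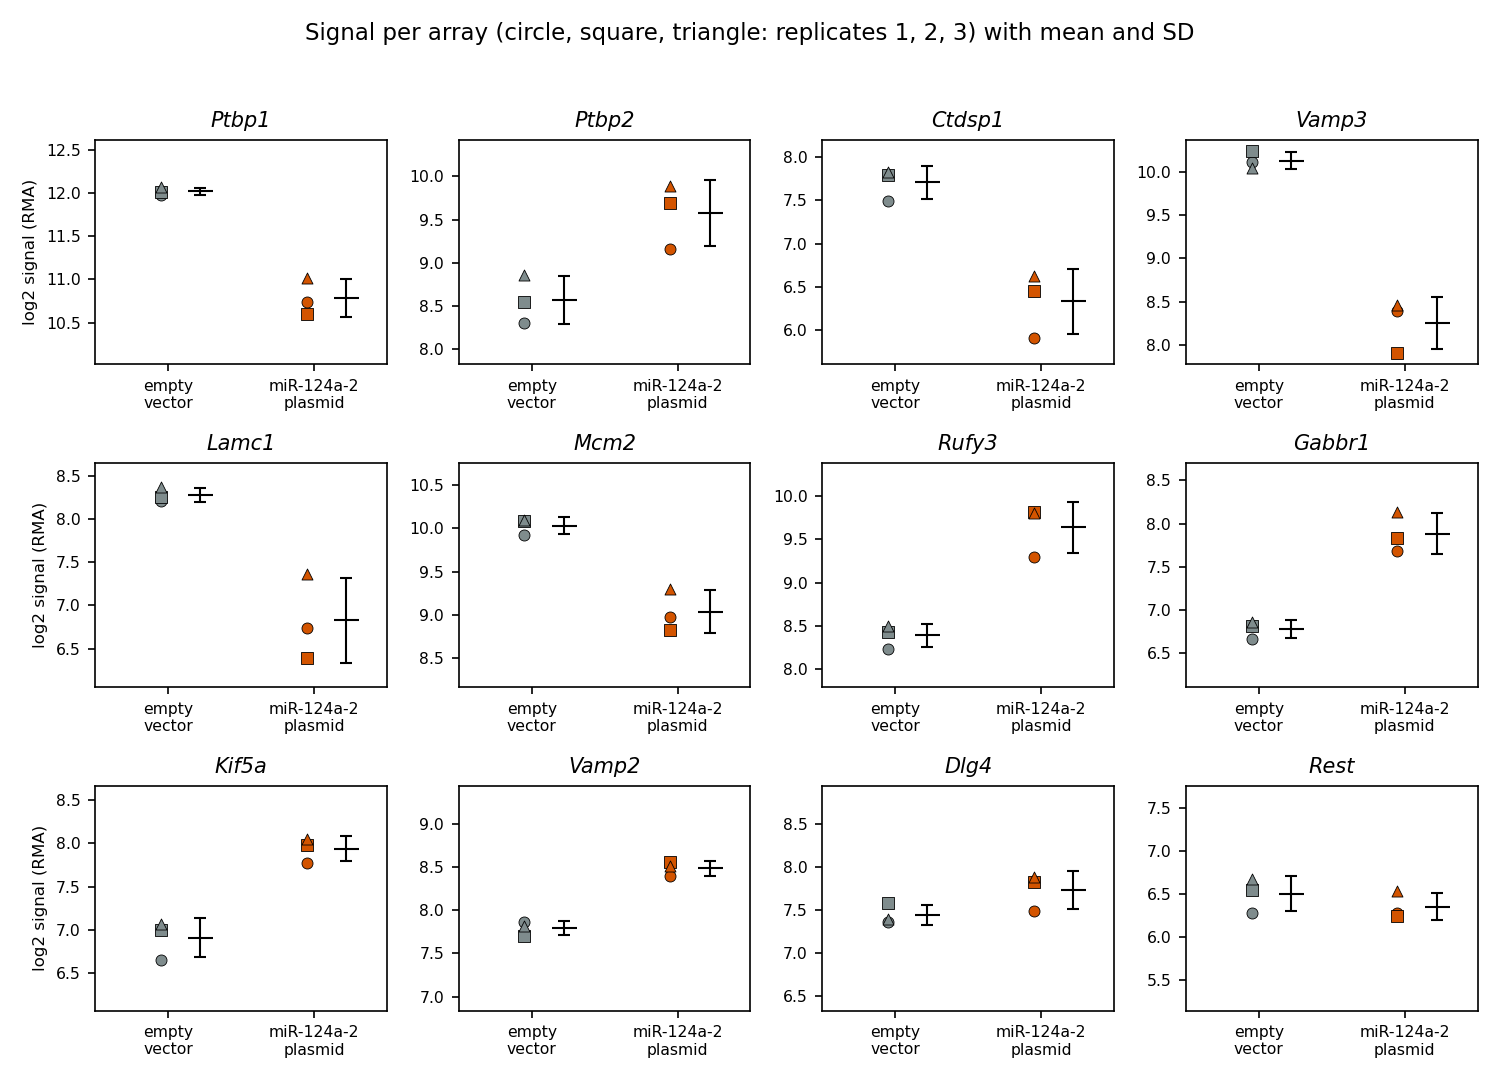
Log2 signal of 12 named genes on each array, with replicates 1, 2 and 3 as circle, square and triangle, and the mean ± SD of 3 arrays beside them. Each vertical axis has its own range, and the groups did not overlap for Ptbp1, Ctdsp1, Vamp3, Lamc1, Mcm2, Rufy3, Gabbr1, Kif5a and Vamp2, which passed, or for Ptbp2, which did not.

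Gene lists fixed beforehand were compared with the other genes. Of 34 reported miR-124 targets, 14 fell, none rose and 20 did not pass (0 rose and 22 fell adjusted over the list alone). Besides Ptbp1 and Vamp3, the collagen-modifying enzyme gene Plod3 fell by 0.97 and the GTPase gene Rhog fell by 0.89, both at adjusted p = 0.0107. The median log2 fold change was -0.63, 32 members were below 0, and the medians within narrow and wide arrays were -0.58 and -0.41. These genes also differed between the array sets, with a median 0.18 higher in wide than in narrow arrays. The list was lower by camera (adjusted p = 6.37e-26; adjusted p = 0.0596 with an estimated correlation, and with that correlation 0.0221 with the array set and 0.171 with the poly-A batch as a block). Of 6 measured transcripts reported as held down by Ptbp1 through splicing, 3 rose, none fell and 3 did not pass (4 rose adjusted over the list alone). The 3 were Gabbr1, Kif5a and the synaptic vesicle gene Vamp2, which rose by 0.69 (adjusted p = 0.0215), and the list median was 0.85 (camera adjusted p = 6.33e-09; adjusted p = 0.0629 with an estimated correlation). None of these 3 passed with the mean of probe sets (0.57, 0.53 and 0.76), and Gabbr1 and Vamp2 did not with the probe set of largest spread (1.16 and 0.84). Whether members of either list were first reported from these samples was not checked, so neither count is taken as independent evidence of direction.

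Of 56 measured RNA-binding regulators of splicing, 2 fell, Ptbp1 and its paralog Ptbp3 (log2 fold change -1.07, adjusted p = 0.0358, -1.14 narrow and -0.74 wide), none rose and 54 did not pass. Adjusted over the list alone, 5 rose and 4 fell, and the list did not differ from other genes (median -0.09, camera adjusted p = 0.214), but passed as lower without empty vector replicate 1 (adjusted p = 0.0229) or miR-124a-2 plasmid replicate 3 (adjusted p = 0.00578, the range over the alternatives being 0.00578 to 0.998). Ptbp3 did not pass with the mean of probe sets (-0.78), with the probe set of largest spread (the same -1.07 as in the main fit) or with median centring. The median of the list was 0.18 higher in wide than in narrow arrays.

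Among 51 neuronal and synaptic genes, 3 rose, none fell and 48 did not pass. The 3 were Gabbr1, Kif5a and Vamp2, whose calls depended on the rule for probe sets as above, and 11 rose with the array set as a block. Adjusted over the list alone, 14 rose and 0 fell. The median was 0.21 (0.16 in the narrow and 0.27 in the wide arrays) with 43 members above 0 (camera adjusted p = 5.29e-10; adjusted p = 0.0749 with an estimated correlation). Of 28 genes known to be repressed by REST, Slc12a5 rose, none fell and 27 did not pass, with 6 higher adjusted over the list alone. Their median was 0.18 (camera adjusted p = 8.68e-06; adjusted p = 0.0596 with an estimated correlation), and 19 of the 28 also stand in another list. Of 16 genes of the REST corepressor machinery, Ctdsp1 fell and 15 did not pass (2 lower adjusted over the list alone; camera adjusted p = 0.258). None of 24 catecholaminergic and neuroendocrine genes passed, with 3 higher adjusted over the list alone. Their largest values were 0.52 for Ddc, which makes dopamine from L-DOPA, and 0.49 for the prohormone-processing gene Cpe, each with 1 of 2 probe sets lower. Cpe passed in 7 of 18 alternatives, among them each of the 3 blocks (replicate number, array set and poly-A batch). That list was higher by camera (median 0.14, adjusted p = 0.00793; adjusted p = 0.118 with an estimated correlation), but not without miR-124a-2 plasmid replicate 3 (adjusted p = 0.0778, from 0.00217 to 0.244 over the alternatives).

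Of 37 cell cycle genes, 4 fell, none rose and 33 did not pass, while 22 were lower adjusted over the list alone. The replicative helicase genes Mcm2, Mcm4 and Mcm5 fell by 1.00, 0.76 and 0.67, and Rrm2, a subunit of ribonucleotide reductase, fell by 0.68 (-0.81 narrow, -0.43 wide; adjusted p of the 4 from 0.0177 to 0.0443). The median was -0.44, with 35 members below 0 and medians of -0.37 and -0.33 within narrow and wide arrays (camera adjusted p = 1.45e-22; adjusted p = 0.123 with an estimated correlation, and with that correlation 0.0221 with the array set and 0.244 with the poly-A batch as a block). Mcm4 did not pass with the mean of probe sets (-0.80), the probe set of largest spread (-0.84) or median centring, nor Rrm2 with the probe set of largest spread (-0.76) or median centring. These genes also differed between the arrays themselves, with a median 0.29 higher in wide than in narrow arrays. None of 7 cyclin-dependent kinase inhibitors passed in either direction, over all genes or adjusted over the list alone (camera adjusted p = 0.685). The values with the largest size were -0.21 for Cdkn2c and -0.15 for Cdkn1b. None of 19 subunits of BAF chromatin remodelling complexes passed by either adjustment (camera adjusted p = 0.819), with -0.78 for Smarcc1 (1 of 4 probe sets higher), which passed with the replicate number or the poly-A batch as a block, and 0.36 for Smarcc2.

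Of 34 integrin, laminin and extracellular matrix genes, 4 fell, none rose and 30 did not pass, with 5 lower adjusted over the list alone. The 4 were Lamc1, Plod3, the integrin gene Itgb1, which fell by 0.87 (adjusted p = 0.0270), and the prolyl hydroxylase gene P4ha1, which fell by 0.63 (adjusted p = 0.0331). Lamc1, Itgb1 and P4ha1 did not pass with the mean of probe sets (-0.88, -0.43 and -0.76) or with the probe set of largest spread (-1.45, -0.85 and -0.89), nor Itgb1 and P4ha1 with median centring. The list was lower by camera (adjusted p = 0.0357; adjusted p = 0.139 with an estimated correlation), with 17 members below 0, a median of -0.02 and a mean of -0.15. That call was lost with the array set as a block (adjusted p = 0.0833) and without empty vector replicate 3 or miR-124a-2 plasmid replicate 1 (medians 0.01 and 0.03, adjusted p = 0.0925 and 0.216) and with replicates 2 and 3 alone (adjusted p from 0.00247 to 0.244 over the alternatives). Of 37 actin cytoskeleton and junction genes, Rhog, Iqgap1 and the focal adhesion gene Tln1 fell, none rose and 34 did not pass (6 lower adjusted over the list alone). These 3 genes, and 3 of the 4 matrix genes that fell, are also reported miR-124 targets, so these falls are not separate from those of that list. Tln1 fell by 1.20 (adjusted p = 0.0158), although 2 of its 3 probe sets, both dim, had higher means, and did not pass with the mean of probe sets (-0.30). The median was -0.11 (camera adjusted p = 3.21e-06; adjusted p = 0.300 with an estimated correlation, and 0.0824 with fry). Genes of this list were 0.15 higher at the median in wide than in narrow arrays.

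None of 17 cholesterol synthesis genes passed by either adjustment, with 0.67 for Hmgcs1, which passed with each of the 3 blocks, and 0.46 for Lss, which passed with the replicate number as a block. The list was higher by camera (median 0.23, adjusted p = 0.00793; adjusted p = 0.734 with an estimated correlation), and its genes were 0.70 higher at the median in the 4 arrays with low poly-A controls than in the replicate 1 arrays. Without empty vector replicate 1 the camera test changed direction (median 0.013, adjusted p = 0.946), and the call was lost without miR-124a-2 plasmid replicates 2 and 3 (adjusted p = 0.107 and 0.269, from 1.02e-08 to 0.946 over the alternatives) and with fry (adjusted p = 0.661). None of 23 interferon response genes passed by either adjustment, with 0.62 for Ifi35, which passed with each of the 3 blocks, and 0.34 for Irf7. Their camera test missed the threshold (adjusted p = 0.0736) and passed with the array set as a block (adjusted p = 0.00695; adjusted p = 0.378 with that block and an estimated correlation, and 0.678 with an estimated correlation alone). It also passed with the replicate number or poly-A batch as a block, with replicates 2 and 3 alone, with the mean of probe sets, and without empty vector replicate 2 (adjusted p = 0.0221) or miR-124a-2 plasmid replicate 1 (adjusted p = 0.000288), the range over the alternatives being 0.000288 to 0.678. None of 23 stress and unfolded protein response genes passed by either adjustment (camera adjusted p = 0.646), with -0.83 for Trib3, which passed with the replicate number or the poly-A batch as a block, and 0.46 for Gadd45a, which passed with the array set as a block, nor did any of 19 genes of the microRNA and nonsense-mediated decay machinery (camera adjusted p = 0.655), with -0.38 for Ago3 and -0.29 for Xpo5.

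Markers of other cell types were measured as well. None of 14 astrocyte, oligodendrocyte and Schwann cell markers passed over all genes, with 0.61 for Cnp and 0.17 for Mog (camera adjusted p = 0.355). Cnp passed adjusted over the list alone and in 6 of 18 alternatives, among them each of the 3 blocks. None of 20 fibroblast, muscle and epithelial markers passed by either adjustment (camera adjusted p = 0.646), with 0.32 for Krt8 and 0.31 for Pdgfra (2 of 3 probe sets lower). None of 10 leukocyte and endothelial markers passed by either adjustment (camera adjusted p = 0.190), with 0.25 for Cdh5 and 0.24 for Cd68, though the list passed without miR-124a-2 plasmid replicate 3 (adjusted p = 0.0399, from 0.0399 to 0.876 over the alternatives).

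**Figure D3:**
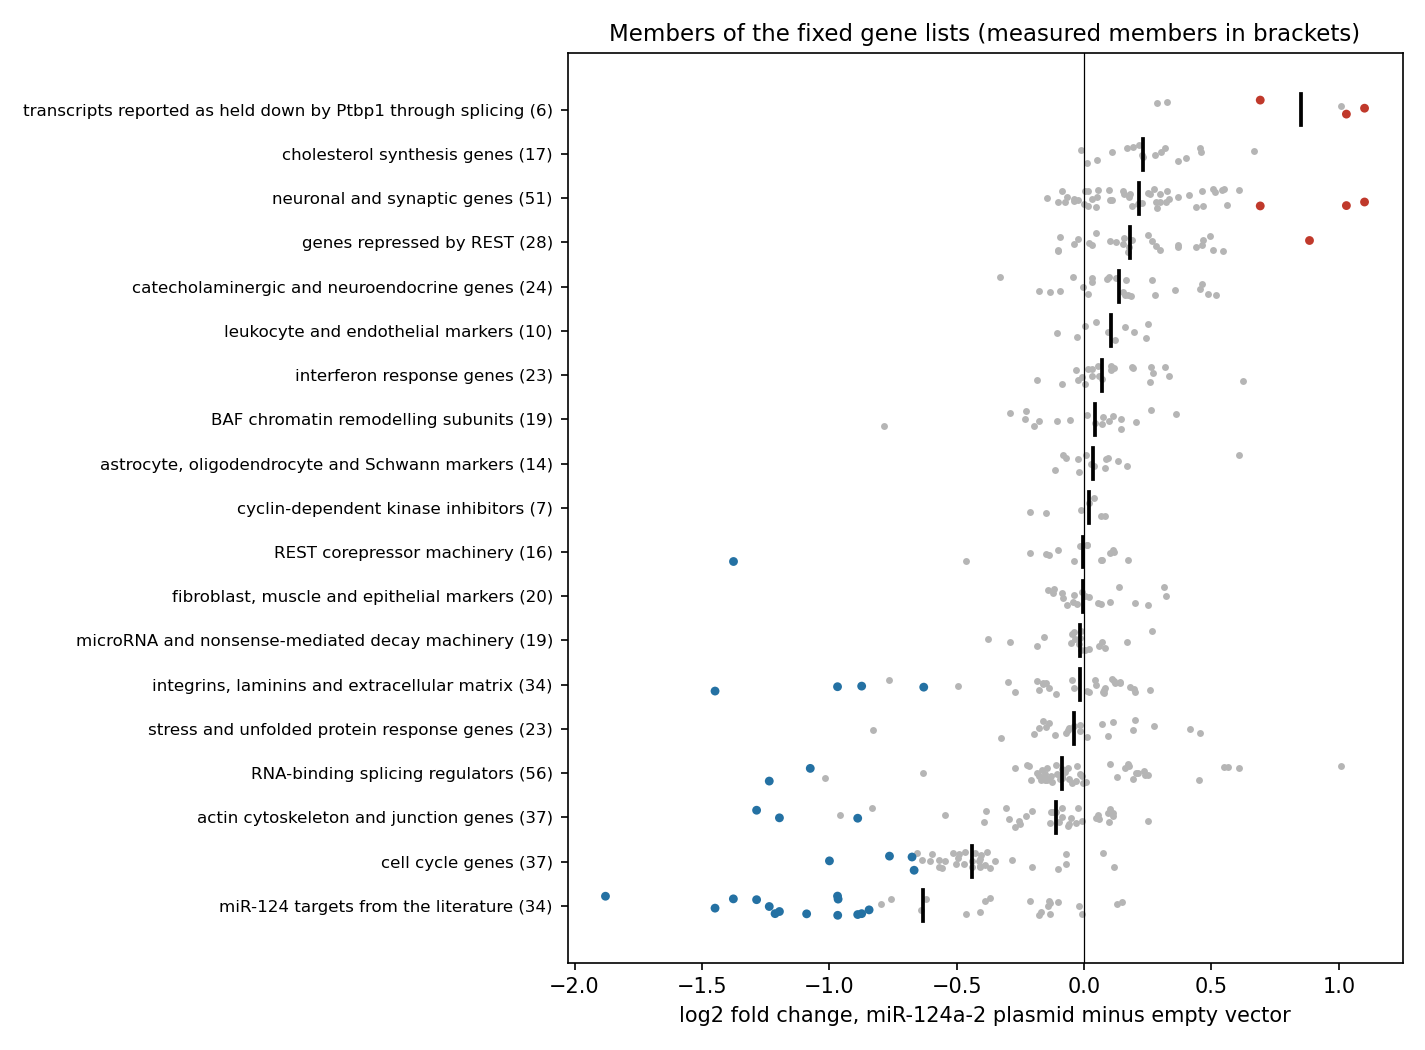
Log2 fold change (miR-124a-2 plasmid minus empty vector) of the measured members of 19 gene lists, with members that fell in blue, members that rose in red, members that did not pass in grey and the list median as a black bar. The median was -0.63 for reported miR-124 targets, -0.44 for cell cycle genes, 0.21 for neuronal and synaptic genes and 0.85 for transcripts reported as held down by Ptbp1.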

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

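A change was seen in probe sets that the comparison of genes did not use. Of 10092 probe sets not tied to exactly 1 gene, 8 changed at an adjusted p under 0.05 over all probe sets, 0 higher and 8 lower with miR-124a-2. An unadjusted p under 0.05 was found in 399, no more than chance alone gives. The 8 are described here. Their log2 fold changes ran from -1.28 to -0.70, with adjusted p from 0.0213 to 0.0417, and they carry no gene name here.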

How the results depend on the processing

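The array set and poly-A batch blocks, their use with an estimated correlation, and the fit of replicates 2 and 3 alone were chosen after the data were seen. Against 165 genes changed (38 higher, 127 lower), counts were 457 (152, 305) with the replicate number as a block, 546 (259, 287) with the array set block, 290 (100, 190) with the poly-A batch block and 0 (0, 0) with replicates 2 and 3 alone (1825 at an unadjusted p under 0.05). They were 99 (23, 76) with median centring, 311 (99, 212) with quantile normalization, 312 (88, 224) with cyclic loess, 270 (66, 204) with an intensity trend and 266 (65, 201) when it was also robust. They were 51 (10, 41) with the probe set of largest spread, 110 (19, 91) with the mean of probe sets, 17 (3, 14) at a threshold of 0.01 and 47 (6, 41) at 2-fold. Leaving out 1 array gave 0 to 343 genes (0 to 38 higher, 0 to 305 lower): 61 and 0 and 0 without empty vector replicates 1, 2 and 3, and 13, 46 and 343 without miR-124a-2 plasmid replicates 1, 2 and 3. Fewer arrays were compared there, and the cause of the other shifts was not tested. All 165 genes passed in both the replicate block and the array set block. Same-numbered arrays paired only in part: correlations of deviations from the group means were 0.54, -3.89e-05 and 0.55 for replicates 1, 2 and 3. The highest between differently numbered arrays of the 2 groups was 0.31. The main fit, which has no block, does not use this pairing. Of 19 lists, 9 passed, and 8 to 10 without 1 array, 7 with fry, and 0 with an estimated correlation (reported targets with median -0.63, adjusted p = 0.0596, neuronal genes with median 0.21, adjusted p = 0.0749). With the estimated correlation, 2 lists passed under the array set block (targets with median -0.50 and cell cycle genes, both at adjusted p = 0.0221), neuronal genes not being one of them (median 0.21, adjusted p = 0.0788), and 0 under the poly-A batch block (targets with median -0.63, adjusted p = 0.171, neuronal genes with median 0.21, adjusted p = 0.215). Over the alternatives their adjusted p ran from 1.25e-28 to 0.171 and from 4.60e-12 to 0.215. Cholesterol genes changed direction by camera without empty vector replicate 1 (median 0.013, adjusted p = 0.946, with medians of 0.013 to 0.49 without 1 array and adjusted p from 1.02e-08 to 0.946 over the alternatives), and Gnao1 turned to -0.37 with the probe set of largest spread (adjusted p = 0.856, from 0.00461 to 0.953). Other values of named genes kept their side of the threshold in 858 cases, lost it in 240 and gained it in 32, and those of lists in 373, 34 and 10, with the cause not tested. Of 40 named genes that passed, 16 lost that with the mean of probe sets, among them Ptbp1 (-0.48, adjusted p = 0.0932), and 21 with the probe set of largest spread. The seed match test was not run.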

Other observations

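The gene groups, the probe set test and the tests below were chosen after the results were seen, except the test without shared probe sets, the test after quantile normalization, and the counts of lists and of genes with diverging probe sets over other splits of the arrays. DNA replication genes outside the fixed cell cycle list stood out among the genes that fell. The origin recognition gene Orc2 fell by 1.08 (adjusted p = 0.00978), the loading factor gene Cdc6 fell by 1.22 (adjusted p = 0.0177), and Dtl, Cdc45, Rpa2 and Mcm10 fell by 0.91, 0.69, 0.66 and 0.53 (adjusted p from 0.0223 to 0.0443). Of 30 further replication genes, not among the 6 that passed and by which the group was noticed, 0 passed over all genes. Adjusted over the list alone 19 were lower, and 28 lay below 0. Their median was -0.40, with values of -0.51 for the clamp loader gene Rfc5 and -0.57 for Gins1. Limma's camera, adjusted over 3 such groups, gave an adjusted p of 1.04e-19, of 0.0574 with an estimated correlation, and of 0.0518 with that correlation and the array set as a block. Members that passed had been set aside, so the count of 0 follows largely from that choice. The group was chosen after the results and is close to the cell cycle list, measured on the same arrays. Its p-values are therefore not independent support. Of 23 nuclear pore genes, 22 lay below 0 with a median of -0.20, and 0 passed over all genes, Nup37 coming nearest at -0.50 (adjusted p = 0.0634). The camera test gave an adjusted p of 1.71e-08, of 0.0838 with an estimated correlation, and of 0.160 with that correlation and the array set as a block. No members of this group were set aside, although it was chosen after the results were seen, so these p-values are not independent support.

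Enzymes of mitochondrial fatty acid oxidation gave a mixed picture. Hadhb, Hadha, Hadh and Acaa2, which act in the later steps of the cycle, fell by 1.00, 0.65, 0.89 and 0.78 (adjusted p from 0.0107 to 0.0233). Of the other 14 measured genes of the pathway, 7 lay below 0, and their median was -0.0044. Their camera test did not pass (adjusted p = 0.154). The values were -0.64 for Acadvl (adjusted p = 0.0529) and 0.22 for Acadm (adjusted p = 0.444).

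Probe sets of the same gene moved apart in some genes. Among 5150 genes with at least 2 probe sets above the median signal, limma's diffSplice found 7 at a false discovery rate under 0.05: Pdlim7, Cdc42, Rufy3, Tor1aip2, Septin6, Rtn4 and Tln1 (188 at an unadjusted p under 0.05, no more than chance alone gives). In Pdlim7, one probe set had a log2 fold change of 1.38 and another -0.65. In the GTPase gene Cdc42, one had 1.42 while 3 brighter ones had -0.06, 0.10 and 0.03, and in Rtn4 one had 1.32 while brighter ones had 0.20 and 0.13. In Septin6 values ran from -0.91 to 1.19, and in Tor1aip2 one probe set had -1.24 and the others 0.13 to 0.22. Leaving out 1 array gave 9, 2 and 2 genes without empty vector replicates 1, 2 and 3, and 9, 6 and 13 without miR-124a-2 plasmid replicates 1, 2 and 3.

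Technical accounts of this divergence were weighed, and differences between narrow and wide arrays did not account for it: all 7 genes passed with the array set as a block, which called 18 genes in all. Without probe sets whose names mark them as shared between genes, 7 of 7 passed. Septin6, Rtn4 and Tln1 had none of these, and in the other genes they were not the ones that diverged most. The calls thus did not rest on them, but this test cannot exclude signal from other genes in the diverging probe sets. A dim probe set that does not follow its gene remains open, since the dimmest probe set departed most from the others in 3 of the 6 genes with at least 3 probe sets (Cdc42, Tor1aip2 and Rtn4), and 2 earlier forms of this test, which counted 4 and 6 genes against that account, could not exclude a dim probe set moving on its own. Splitting the 6 arrays otherwise gave up to 57 genes, for narrow against wide arrays, against 7 for the real groups (2 of 10 splits as large), and 10 splits are too few for a share under 0.05. A shift between transcript forms with different exons or 3′ ends, as a splicing regulator such as Ptbp1 might cause, is a hypothesis these values leave open, since the positions of the probes were not used here.

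More genes fell than rose (127 against 38, or 23.0% higher), a balance of calls past adjustment, since 934 of the 1988 genes at an unadjusted p under 0.05 were higher (47.0%), and without 1 array the share was 46.2%, 23.9% and 11.1% of 13, 46 and 343 calls (miR-124a-2 plasmid replicates 1, 2 and 3) and 16.4% of 61 (empty vector replicate 1), with 0 calls in limma without empty vector replicates 2 and 3 (1285 and 1313 genes at an unadjusted p under 0.05). With the array set as a block 47.4% of calls were higher, as would be seen if array differences had hidden more rises than falls. The share was 33.3% with the replicate number and 34.5% with the poly-A batch as a block, so this reading rests on the array set block. Falls still outnumbered rises under median centring, quantile normalization and cyclic loess. The share was highest with quantile normalization, at 31.8% against 23.0% in the main fit, so a part of the balance may depend on scaling. Among calls of at least 2-fold with the array set block the share was 22.0%, and the main fit had 6 higher and 41 lower. Lowering of transcripts by the expressed microRNA may underlie the larger falls. This share cannot decide that, since any cause of more large falls than rises would give it, and no target sites were examined. In other splits of the 6 arrays the highest count was 0, against 165 for the real groups (1 of 10 splits as large), which are too few splits for a share under 0.05.

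Unlike the plasmid groups, which the labels fix, the split into narrow and wide arrays was drawn from the spread of these same values. Genes therefore differ between its sets in part by definition, and its counts cannot be set evenly against those of the plasmid. The split gave 4046 genes at an unadjusted p under 0.05, against 1988 for the plasmid, though 0 passed adjustment (smallest adjusted p = 0.0600). It called as many lists as the real groups did (9 and 9, 2 of 10 splits as large, the other 9 splits calling 2 to 9 lists, and 9 lists passed with the array set as a block). Scaling left over after RMA does not account for all of the split, since 3483 genes had an unadjusted p under 0.05 after quantile normalization. Only 2429 of them were among the 4046, so a part of the split may depend on scaling. Batches marked by the poly-A controls placed 1 of 6 arrays otherwise. The batches and the array sets differ in size, so at least 1 array had to be placed otherwise. This comparison therefore cannot exclude that the split follows those batches in part. A difference in RNA or labelling is consistent with the 18S controls, whose lowest narrow value lay 0.36 above the highest wide one. No biological explanation was tested, since the labels name no culture difference between these arrays.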
